A study of Mus musculus with 17 samples.

How the data were processed

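CD8+ T cells from brain and blood of APP-PS1 and WT mice were profiled by RNA sequencing, 17 libraries in 4 groups. Per the labels' protocols, brains were dissociated mechanically and myelin was removed on a density gradient, while blood was treated with red cell lysis buffer; cells were then incubated with fluorescent antibodies. How the CD8+ cells were then separated is not given in the sources used here. The deposited values are whole-number counts per gene and library, not normalized. The submitters' processing notes name FastQC, Bowtie2 2.2.2, HTSeq 0.11.2, DESeq2 and the build GRCm38, without their roles or order. The strand setting, the annotation release and any use of molecular identifiers are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart with certainty. For example, the ratio of Rps27 to Rps27rt counts stayed between 0.914 and 1.13 in all libraries.

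Groups were taken from the labels. No label pairs brain and blood libraries, so no paired analysis was made. Same-group libraries were compared by chi-square over genes; over 29 pairs the statistic per degree of freedom ranged from 2.59 to 5.69 and 0 pairs were identical, so each library was counted once. Of 48709 genes, 48349 matched GENCODE M21 by identifier, which supplied coordinates on the same build.

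Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr (about 117 CPM in at least 3 libraries, 2366 genes kept), robust dispersions (common biological coefficient of variation 0.370), and quasi-likelihood F tests with 1 mean per group over all libraries. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its absolute value over the square root of F. CPM are on total counts, with SD between libraries. Gene lists with at least 3 tested genes (14 of 28 lists) were tested with camera at a preset correlation of 0.01, and adjusted over 14 lists; of 422 listed symbols, 417 matched the file and 5 were not analysed here. Summed CPM and genes below the filter were compared by exact two-sided permutation tests in SciPy 1.17.1. Figures were drawn with matplotlib 3.10.9. A fold against a group at 0 is a lower bound against 3 counts over that group. Poisson intervals and floors cover counting error only. Bootstrap intervals resample the genes of the lists, so they do not measure the spread between libraries.

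Before the data were examined, the design, the gene lists and the rule for named genes were fixed. The rule takes, per comparison, up to 10 called genes per direction with the largest changes, at least 20 CPM and no overlap between groups (without predicted genes and receptor variable segments), up to 4 members of each list (called ones first, otherwise those with the highest CPM), and a fixed set of 23 residency, checkpoint, effector, homing, lineage and transgene symbols, with sex-linked genes as a label check. Of the genes it gives, 2 are not reported here. Other called genes named for the contrast averaged over strains and the genes named as holding most of a marker sum were chosen after their values were seen. That contrast, the fit without 2 libraries that stood apart, the sums of residency, naive, interferon, effector and T cell receptor lists and the tests below the filter were also added after the data were seen. Alternatives were RLE size factors, DESeq2 1.42.0, limma voom with quality weights (limma 3.58.1), 2 other filters, non-robust fits, only the groups compared, thinning to 27646 counts, sex as a term, female libraries only, fits without mitochondrial, ribosomal and haemoglobin genes, an estimated correlation, fry, a fold threshold and leaving out each library.

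The steps were tested on simulated data with 2366 genes, of which 200 were changed. For WT brain against blood, 32% of genes changed 2-fold and 86% changed 4-fold were recovered; for APP-PS1 brain against blood, 12% and 52%; for APP-PS1 against WT blood, 18% and 54%. Of 2166 unchanged genes, 2 to 6 were called. Changing 200 genes together eases the Benjamini-Hochberg threshold, so the recovered shares are too high for comparisons in which few genes change. With no change simulated, 4.29% of 280 list tests had an unadjusted p under 0.05. Genes were drawn independently there, so this rate does not cover lists whose genes vary together.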

Results

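RNA sequencing counts were obtained for CD8+ T cells, the cytotoxic T lymphocyte lineage, from the brain and the blood of 2 mouse strains. APP-PS1 mice are a transgenic amyloid model of Alzheimer's disease, and wild type (WT) mice were the controls. The 17 libraries comprised 5 from WT brain, 5 from WT blood, 4 from APP-PS1 brain and 3 from APP-PS1 blood. All WT libraries came from females, whereas APP-PS1 brain held 3 male libraries and 1 female library and APP-PS1 blood held 2 male libraries and 1 female library, so sex and strain largely coincided. The design text names 7 APP-PS1 and 10 WT mice, and no label ties a brain library to a blood library of one animal. The p-values therefore measure the spread between these samples, which may in part be technical.

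The libraries were shallow. The total per library ranged from 27646 to 214670 counts, with means of 119048 ± 58187 (SD, n = 5) in WT blood, 104436 ± 47184 (SD, n = 5) in WT brain, 74254 ± 42732 (SD, n = 4) in APP-PS1 brain and 42164 ± 3755 (SD, n = 3) in APP-PS1 blood. The 3 APP-PS1 blood libraries, at 39055 to 46336 counts, were all shallower than the 5 WT blood libraries, at 62604 to 214670 counts. Of 48709 genes listed, 13539 had at least 1 count and 2366 passed the expression filter and were tested. Genes of the T cell receptor complex were abundant in all groups: Cd8a reached 718 ± 188 CPM (counts scaled to the library total; SD, n = 5) in WT brain and 518 ± 97.0 (SD, n = 5) in WT blood. No Cd4 count occurred in any library, which allows up to 5.04 CPM over the WT blood group and up to 23.7 CPM over the APP-PS1 blood group, counting error only. Xist, the RNA that coats the inactive X chromosome, had 419 counts in the 12 libraries labelled female and 2 in the 5 labelled male. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 38 counts in the 5 male libraries and 10 in 6 of the 12 female ones, up to 3 in WT blood replicate 2, against 2 in APP-PS1 blood replicate 2, labelled male. WT blood replicate 4, labelled female, had 1 Xist count and no count for the Y-linked genes.

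**Figure D1:**
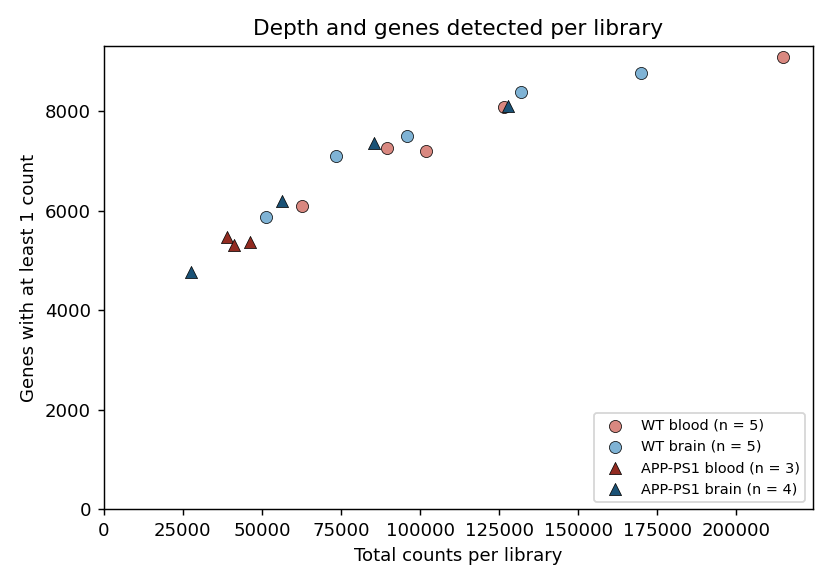
Total counts per library (x axis) against the number of genes with at least 1 count (y axis), 1 point per library, circles for WT and triangles for APP-PS1. Genes detected ranged from 4781 in the shallowest library to 9102 in the deepest.

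In WT mice, brain CD8+ T cells were compared with blood CD8+ T cells to ask how cells in the tissue differ from circulating ones. Brain was dissociated and put on a density gradient, and blood was treated with red cell lysis buffer. Tissue and processing therefore cannot be told apart in any comparison of brain with blood. Brain libraries had lower levels of Klf2 and Klf3, transcription factors of quiescent, recirculating T cells, and of S1pr1, the receptor that guides lymphocyte egress into the circulation. They had higher levels of Cxcr6, a chemokine receptor of tissue T cells, of the chemokine Xcl1, of the interferon-induced exonuclease Isg20, of the phosphatase Dusp2 and of Pmepa1, a target of TGF-beta signalling. Klf2 averaged 142 ± 34.0 CPM (SD, n = 5) in brain and 772 ± 269 CPM (SD, n = 5) in blood, a log2 fold change of -2.46 (SE 0.33, adjusted p = 1.29e-06). Klf3 fell by 2.41 on the log2 scale (SE 0.36, adjusted p = 1.27e-05) and S1pr1 by 3.59 (SE 0.85, adjusted p = 0.0151). Xcl1 averaged 420 ± 114 CPM in brain and 75.2 ± 57.2 CPM in blood, with a log2 fold change of 2.34 (SE 0.40, adjusted p = 0.000121). The log2 fold change was 2.34 for Isg20 (adjusted p = 0.000880), 2.13 for Dusp2 (adjusted p = 0.0107), 1.21 for Cxcr6 (adjusted p = 0.0130) and 2.47 for Pmepa1 (adjusted p = 0.0412).

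In all, 18 of 2366 genes differed between WT brain and WT blood, 5 higher and 13 lower in brain, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among effector genes, the chemokine Ccl5 fell by 1.11 on the log2 scale (adjusted p = 0.000121), from 43113 ± 8209 CPM (SD, n = 5) in blood to 20850 ± 3007 CPM (SD, n = 5) in brain, and granzyme M (Gzmm) fell by 3.49 (adjusted p = 0.000481). Granzymes Gzmb and Gzmk had log2 fold changes of -0.45 and 0.05 that did not pass (adjusted p = 0.899 and 0.989). Gzma, at -3.34, did not pass either (adjusted p = 0.0962), and WT blood replicate 5 alone held 2131 CPM of it. The GTPase Arl4c fell by 1.55 (adjusted p = 0.00566) and a gene listed as Pde2a_1 by 3.63 (adjusted p = 0.0307). Also lower were Igkc, the immunoglobulin kappa constant region of B cells, which fell by 2.12 (adjusted p = 0.0307), and 4 haemoglobin genes, Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, which fell by 3.74 to 4.06 on the log2 scale. Reads of the 2 alpha and of the 2 beta haemoglobin genes cannot be told apart with certainty. Several of these calls ended when a single library was left out. The call of Cxcr6 ended without WT blood replicate 2 or 3 or WT brain replicate 3 (adjusted p up to 0.0965). That of S1pr1 ended without WT brain replicate 1 or 4 (up to 0.0822), that of Dusp2 without WT brain replicate 5 (0.0519) and that of Hbb-bt without WT brain replicate 1 (0.0514). The call of Igkc ended without WT blood replicate 1, 2 or 4 or WT brain replicate 1, 4 or 5 (up to 0.116). That of Pde2a_1 ended without WT blood replicate 2, 3, 4 or 5 or WT brain replicate 1, 2, 3 or 4 (up to 0.152). The call of Pmepa1 ended without any one WT blood library, without WT brain replicate 1, 3 or 4 or without APP-PS1 brain replicate 2, 3 or 4 (up to 0.266).

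Of 14 gene lists tested in WT, 7 passed. Of 15 tested genes known to be low in tissue-resident memory T cells, 13 had negative log2 fold changes, with a median of -1.26 (camera, adjusted p = 7.88e-17), and 4 of them were called, among them Klf2, Klf3 and S1pr1, or 9 when adjusted over the list alone. Of 14 tested genes known to be high in such cells, 10 were positive, with a median of 1.12 (adjusted p = 9.90e-08), and 3 were called (Cxcr6, Isg20 and Xcl1), or 7 when adjusted over the list alone. Of 11 tested genes of naive T cells, all had negative values, with a median of -1.90 (adjusted p = 2.70e-16), and 3 were called, among them Klf2 and S1pr1, or 8 when adjusted over the list alone. Of the naive list, 5 members are also on the first. A library gives 1 value per gene, so a smaller share of naive cells in brain cannot be told apart from a change within cells. This holds for both strains and was not tested. Of 14 tested type I interferon response genes, 13 were positive, with a median of 0.88 (adjusted p = 6.58e-10), although Isg20 alone was called gene by gene, or 5 genes when adjusted over the list alone. Effector genes fell as a list, with a median of -0.46 over 17 genes (adjusted p = 0.000108), but not with only the groups compared (median 0.02, adjusted p = 0.239) or after thinning (-0.71, adjusted p = 0.0648). With an estimated correlation the adjusted p was 0.000597 for the first list, 0.00248 for the second, 0.000623 for naive, 0.000177 for interferon and 0.0162 for effector genes. The 4 tested checkpoint genes, among them Pdcd1 at 1.33, passed narrowly as a list (median 0.71, adjusted p = 0.0461), and the median turned to -0.23 over 16 genes without a filter (adjusted p = 0.828) and to -0.54 over 15 genes with a filter of 5 CPM in 3 libraries (adjusted p = 0.914). The call was also lost with an estimated correlation (adjusted p = 0.0763), with voom (0.0747), with non-robust fits (0.0510), with female libraries only (0.446), without mitochondrial, ribosomal and haemoglobin genes (0.0528) and without 2 libraries that stood apart (0.100). Single libraries ended it too: it was lost without any one WT blood library, without WT brain replicate 1, 3 or 5 and without APP-PS1 brain replicate 2 (adjusted p up to 0.165).

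Lists that did not pass in WT were chemokines and receptors (adjusted p = 0.602, median -0.05 with a mean of 0.11 and an upward test), adhesion molecules (adjusted p = 0.792) and immediate early genes (adjusted p = 0.792, median 0.34 with a mean of 0.07 and a downward test). Nor did heat shock genes (adjusted p = 0.621), T cell receptor genes (adjusted p = 0.792), glycolysis (adjusted p = 0.792, median 0.07 with a mean of -0.02 and a downward test) or lipid genes (adjusted p = 0.792). Immediate early genes passed as lower in brain without a filter, with a median of -0.78 over 23 genes (adjusted p = 0.0377), and with a filter of 5 CPM in 3 libraries, with a median of -0.81 over 21 genes (adjusted p = 0.0105). TGF-beta and cell cycle lists each had 2 tested genes and were not tested as lists, and the transgene list had none.

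Several classic residency genes lay below the expression filter and were compared by exact two-sided permutation tests on CPM, 9 in one family. Itga1, the integrin alpha-1 chain, averaged 129 ± 76.4 CPM (SD, n = 5) in WT brain and 10.8 ± 10.8 CPM (SD, n = 5) in WT blood, with every brain library above every blood library (exact p = 0.00794, the smallest possible, adjusted p = 0.0714). Itgae, the CD103 integrin chain, had 20 counts in WT brain and 2 in WT blood (exact p = 0.167, adjusted p = 0.300). S1pr5, another egress receptor, had 2 counts in brain and 44 in blood (exact p = 0.0873, adjusted p = 0.300). Zfp683, Ctla4, Lag3, Ifng and App had at most 29 counts per WT group (adjusted p of at least 0.300). Cd69, an activation and residency marker, had a log2 fold change of -0.94 in WT that did not pass (adjusted p = 0.776).

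In APP-PS1 mice, the same comparison of brain with blood gave 13 called genes, 5 higher and 8 lower in brain. Klf3 averaged 42.8 ± 22.0 CPM (SD, n = 4) in brain and 741 ± 183 CPM (SD, n = 3) in blood, a log2 fold change of -3.91 (SE 0.48, adjusted p = 9.66e-08). Klf2 fell by 2.88 (SE 0.40, adjusted p = 2.04e-06), and the lymph node homing receptor Ccr7 fell by 4.47 (SE 0.68, adjusted p = 1.21e-05). The immediate early gene Ier2 fell by 2.15 (adjusted p = 0.000911) and Lef1, a transcription factor of naive T cells, by 2.13 (adjusted p = 0.00969). Higher in brain were Cxcr6 by 1.87 (SE 0.40, adjusted p = 0.00671), Isg20 by 3.49 (SE 0.75, adjusted p = 0.00734), Efhd2 by 1.80 (adjusted p = 0.0379), the cytokine signalling inhibitor Socs1 by 2.94 (adjusted p = 0.0437) and the clathrin light chain Clta by 3.89 (adjusted p = 0.0441). Over all APP-PS1 blood libraries Isg20 had 3 counts, Socs1 4 and Clta 1, at or near the floor of 3 counts, so the sizes of these folds are uncertain. Pdcd1, which encodes the inhibitory receptor PD-1, had 34 counts in brain and 0 in blood, at least 5.93-fold higher against a floor of 3 counts over the group, and narrowly missed the threshold (adjusted p = 0.0584). The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs also fell (adjusted p = 0.0244, 0.0114 and 0.000795). Without APP-PS1 blood replicate 2 the calls of Cxcr6 (adjusted p = 0.0961), Isg20 (0.0701), Lef1, Efhd2, Socs1, Clta, Hba-a1 and Hba-a2 ended. The call of Lef1 also ended without APP-PS1 brain replicate 4 (adjusted p up to 0.102), and that of Efhd2 without APP-PS1 blood replicate 3 or APP-PS1 brain replicate 1 or 3 (up to 0.164). The call of Socs1 also ended without APP-PS1 blood replicate 1, APP-PS1 brain replicate 1 or 4 or WT brain replicate 1 (up to 0.251). The call of Clta also ended without APP-PS1 blood replicate 3, APP-PS1 brain replicate 2 or 3 or WT brain replicate 1 (up to 0.215), and that of Hba-a1 without APP-PS1 brain replicate 1, 2 or 3 (up to 0.102). Itgae had 11 counts in APP-PS1 brain and 0 in blood (exact p = 0.229, two-sided), where 4 against 3 libraries cannot go below 0.0571. Itga1 averaged 51.04 ± 36.5 CPM (11 counts) in APP-PS1 brain and 15.3 ± 13.3 CPM (2 counts) in APP-PS1 blood, with overlap between the groups (exact permutation p = 0.229). S1pr1, Gzma, Gzmb, Gzmk and Cd69 had log2 fold changes of -1.99, -2.01, 0.89, 1.07 and 0.67 that did not pass (adjusted p of at least 0.435).

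The residency, naive and interferon lists moved the same way in APP-PS1 mice. Residency-low genes had a median of -1.28 with 12 of 15 negative (adjusted p = 2.97e-12), and residency-high genes a median of 1.31 with 11 of 14 positive (adjusted p = 1.55e-05). Naive genes had a median of -2.05 with 10 of 11 negative (adjusted p = 2.96e-14) and interferon genes a median of 1.75 with 14 of 14 positive (adjusted p = 1.37e-11). Adjusted over the list alone, 6, 4, 7 and 9 genes of these lists were called in the direction of the list, and Vps37b of the residency-high list was called against it. Over all tested genes 3 (Klf2, Klf3, Ccr7), 2 (Cxcr6, Isg20), 3 (Klf2, Lef1, Ccr7) and 1 (Isg20) were called. With an estimated correlation the adjusted p was 0.00155, 0.0139, 0.00130 and 7.13e-05, and the residency-high list did not pass with female libraries only (median 1.56, adjusted p = 0.0864). Immediate early genes fell as a list, with a median of -0.30 (adjusted p = 0.0220, and adjusted p = 0.0424 with an estimated correlation), and this call ended with no filter (adjusted p = 0.0587), with female libraries only (0.331), without APP-PS1 blood replicate 2 (0.204) and without APP-PS1 brain replicate 4 (0.0592). Effector genes did not pass (median -0.08, adjusted p = 0.454), nor did checkpoint genes (median 0.83, also with Pdcd1 at its bound, adjusted p = 0.0526), which passed without some single libraries (adjusted p down to 0.0288 without APP-PS1 brain replicate 3). Chemokine, adhesion, T cell receptor, glycolysis, lipid and heat shock lists did not pass (adjusted p of at least 0.642), and the heat shock list had a median of 0.23 with a downward test. The count of called genes depended on the blood libraries, with 8 without APP-PS1 blood replicate 2 and 22 without replicate 3.

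**Figure D2:**
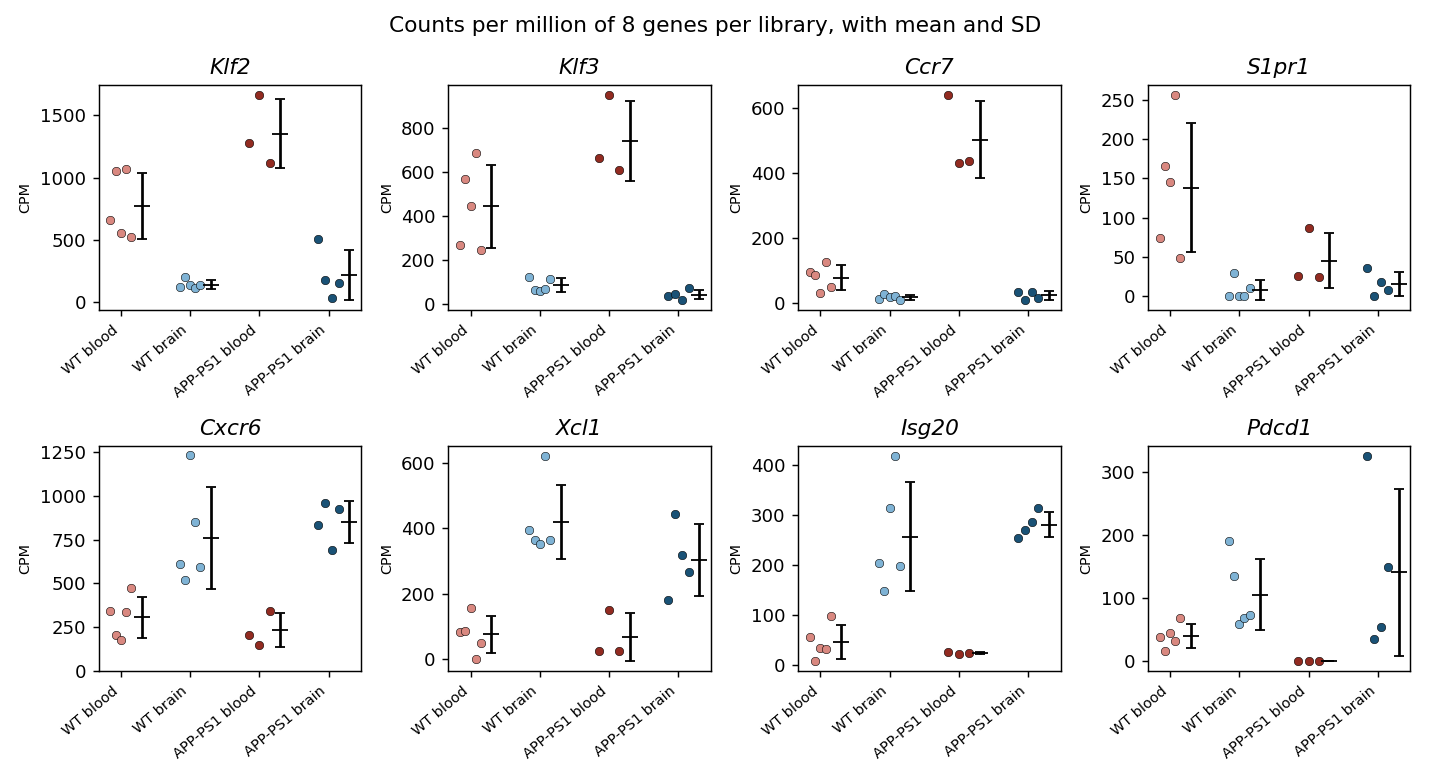
CPM (y axes) of 8 genes in each of the 17 libraries by group (x axes); points are libraries, and bars give the mean ± SD of each group. Klf2, Klf3, Ccr7 and S1pr1 lie higher on average in blood and Cxcr6, Xcl1 and Isg20 higher in brain; Pdcd1 has 0 counts in the 3 APP-PS1 blood libraries.

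The brain against blood changes of the 2 strains, which share no library, were set side by side. Of the 24 genes called in either strain, 23 had the same sign in both, and Igkc was the exception. Cxcr6 and Isg20 were called higher in both strains, and Klf2, Klf3, Hba-a1, Hba-a2 and Hbb-bs were called lower in both. The haemoglobin genes may reflect RNA of red cells left in both blood groups, and so may not bear on CD8+ T cells. Independent lists would share 0.0106 and 0.0440 genes. The lists are not independent, since both comparisons came from a shared fit with a shared dispersion per gene. Reads of the alpha haemoglobin genes also cannot be told apart with certainty. The expected numbers are therefore too low a reference to measure how far the strains agree. Across all 2366 genes, which are not independent replicates, Pearson's r between the log2 fold changes was 0.364 and Spearman's rho 0.253. In GRCm38, Klf2 lies on chromosome 8 from 72319033 to 72321656 and Klf3 on chromosome 5 from 64803388 to 64832901. Cxcr6 lies on chromosome 9 from 123806475 to 123811760 and Isg20 on chromosome 7 from 78913424 to 78920396, all protein coding.

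**Figure D3:**
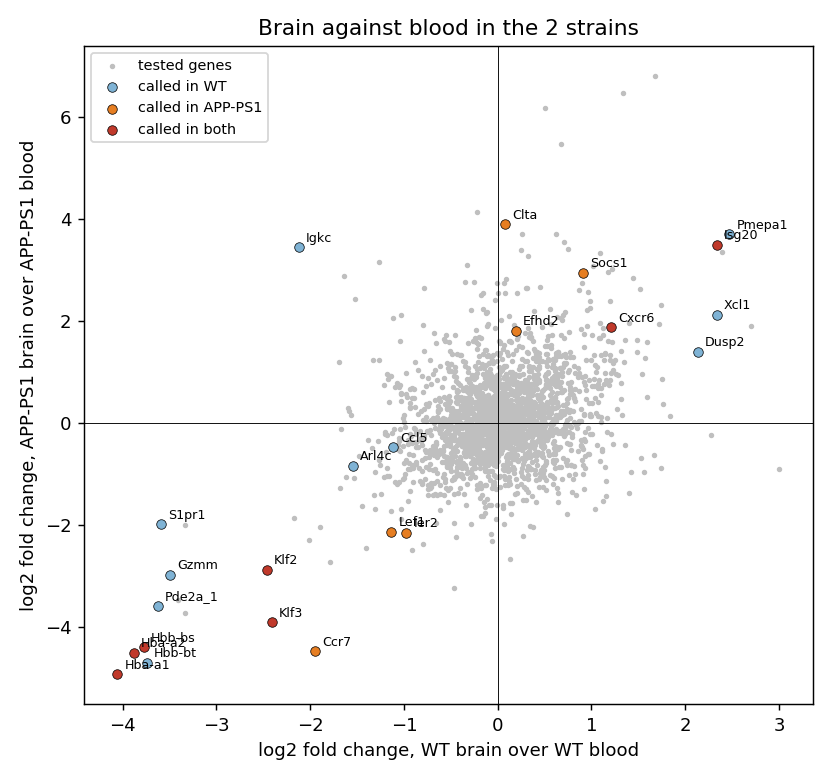
Log2 fold change of brain over blood in WT (x axis) and in APP-PS1 (y axis), 1 point per gene, with called genes coloured and named. Klf2, Klf3 and haemoglobin genes lie in the lower left, Cxcr6 and Isg20 in the upper right, and Igkc alone among the called genes in the upper left.

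Averaging brain against blood over both strains, a contrast added after the counts per strain were seen, gave 62 called genes, 30 higher and 32 lower in brain. Interferon-induced genes were prominent among the higher ones: Isg15 (log2 fold change 1.83, adjusted p = 0.00554), Ifit1 (2.87, adjusted p = 0.0105), Ifit3 (1.79, adjusted p = 0.0405), Irf9 (2.14, adjusted p = 0.0309) and Ifi27l2a (1.03, adjusted p = 0.00806) joined Isg20. All 14 tested interferon genes were positive, with a median of 1.31 (camera, adjusted p = 3.88e-15, and adjusted p = 1.45e-05 with an estimated correlation). Of these, 6 were called, or 12 when adjusted over the list alone. Checkpoint genes also passed as a list (median 0.69, adjusted p = 0.0157, and 0.0425 with an estimated correlation), but not without a filter (adjusted p = 0.472 over 16 genes), with the 5 CPM filter (0.369 over 15 genes) or with female libraries only (0.266). Immediate early genes did not pass (median -0.27, adjusted p = 0.0798), but passed as lower under several alternatives (adjusted p down to 0.00258, without a filter). Effector genes passed as lower (median -0.55, adjusted p = 0.00964), but not with an estimated correlation (adjusted p = 0.0754), after thinning, where the median turned to 0.11 (adjusted p = 0.601), or without WT blood replicate 5, where it turned to 0.04 (adjusted p = 0.106). Pdcd1 rose, with 121 ± 92.6 CPM (SD, n = 9) in brain and 24.8 ± 25.2 CPM (SD, n = 8) in blood (adjusted p = 0.00797). The residency genes Litaf and Rgs1 rose by 4.24 (adjusted p = 0.00806) and 1.44 (adjusted p = 0.0261), and the integrin chain Itgb1 by 1.01 (adjusted p = 0.0174). Vps37b, also on the residency-high list, went the other way and fell by 1.93 (adjusted p = 0.0338). Among naive genes, Ccr7, Lef1, Tcf7, Satb1 and Dapl1 fell by 3.21, 1.64, 1.13, 1.97 and 3.44, with adjusted p of 9.32e-07, 0.000249, 0.0109, 0.0194 and 0.0132. The sialic acid enzyme gene Cmah fell by 3.54 (adjusted p = 0.00368) and Klrg1, a marker of terminal effector cells, by 2.02 (adjusted p = 0.0314). With voom and quality weights 36 genes were called, 9 higher and 27 lower, and Isg15, Ifit1, Ifit3, Irf9, Pdcd1 and Rgs1 were not among them. Single libraries ended several calls: Ifi27l2a without APP-PS1 blood replicate 2 (adjusted p = 0.0877) and Tcf7 without APP-PS1 blood replicate 3 (0.0618). Satb1 lost its call without APP-PS1 blood replicate 3 or WT brain replicate 2 (up to 0.0784). Itgb1 lost it without APP-PS1 blood replicate 1 or 2 or APP-PS1 brain replicate 4 (up to 0.0935). Rgs1 lost its call without any one APP-PS1 blood library, APP-PS1 brain replicate 2 or 4 or WT brain replicate 4 (up to 0.11). Irf9 lost it without any one APP-PS1 blood library, APP-PS1 brain replicate 1 or 4, WT blood replicate 2 or WT brain replicate 3 (up to 0.113). Klrg1 lost it without APP-PS1 blood replicate 1 or 3, APP-PS1 brain replicate 2, 3 or 4 or WT brain replicate 2 or 5 (up to 0.0760). Vps37b lost it without APP-PS1 blood replicate 2 or 3, APP-PS1 brain replicate 2 or 3, WT blood replicate 3 or WT brain replicate 2, 4 or 5 (up to 0.127). Ifit3 lost it without any one APP-PS1 blood library, APP-PS1 brain replicate 2, 3 or 4, WT blood replicate 1 or 5 or WT brain replicate 1, 4 or 5 (up to 0.144).

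Markers of other cell types were summed per library, to see whether RNA of other cells differed between the groups. The 4 tested haemoglobin genes had a median log2 fold change of -3.83 in WT and -4.61 in APP-PS1 (camera, adjusted p = 7.83e-18 and 5.00e-15). Their red cell and platelet list summed to 6550 ± 3798 CPM (SD, n = 5) in WT blood and 424 ± 282 CPM (SD, n = 5) in WT brain (exact p = 0.00794, two-sided permutation, adjusted p = 0.0225 over 17 lists). B cell markers summed to 357 ± 148 CPM in WT blood and 83.9 ± 12.4 CPM in WT brain (exact permutation p = 0.00794, adjusted p = 0.0225). The sums of most other cell type lists were held largely by 1 gene each that was also present in blood, and so do not show whether RNA of those cells differed. In WT brain, Thy1 held 528 of 532 neuron counts, Bsg 127 of 139 endothelial counts, Cnp 84 of 120 oligodendrocyte counts and Ccr2 115 of 116 monocyte and neutrophil counts, and in WT blood these genes held 503, 132, 110 and 143 counts. The most specific microglia genes were nearly absent: of 7 such genes, P2ry12, Tmem119, C1qa and Trem2 had 0 counts in brain and in blood, and C1qb, C1qc and Csf1r had 5 counts together, all in brain. The summed residency-high list was 3367 ± 826 CPM in WT brain and 1529 ± 320 CPM in WT blood, and the summed interferon list 3291 ± 209 and 1711 ± 323 CPM (exact permutation p = 0.00794, adjusted p = 0.0225 for both). Residency-low genes summed to 2313 ± 405 CPM in WT brain and 4689 ± 954 CPM in WT blood and effector genes to 32893 ± 3475 and 55414 ± 8311 CPM, with the same exact p and adjusted p. The effector sum was mainly Ccl5, which held 11012 of 17382 counts in WT brain and 27562 of 34867 in WT blood, and so does not show a fall of effector genes in general. Naive genes, at 1411 ± 149 and 3236 ± 1052 CPM, and T cell receptor genes, at 15472 ± 780 and 13908 ± 1362 CPM, did not pass after adjustment (exact permutation p = 0.0317 and 0.0635, adjusted p = 0.0771 and 0.0981). Nor did CD4 and regulatory T cell markers, at 176 ± 114 and 69.3 ± 44.1 CPM, or gamma-delta T cell markers, at 465.6 ± 121 and 294 ± 105 CPM, both higher in WT brain (exact permutation p = 0.0476, adjusted p = 0.0810 for both). In APP-PS1 mice, where no sum can go below an exact permutation p of 0.0571, interferon genes summed to 3746 ± 386 CPM (SD, n = 4) in brain and 1276 ± 211 CPM (SD, n = 3) in blood. Red cell and platelet markers, at 204 ± 140 CPM in APP-PS1 brain and 6083 ± 2758 CPM in APP-PS1 blood, were at the same smallest exact p (adjusted p = 0.121). So was the monocyte and neutrophil list, but Ccr2, a receptor that T cells also carry, held 56 of its 58 counts in brain and 3 of 3 in blood. The broader microglia list was higher in blood at that p, with Cst3 holding 59 of 99 counts in brain and 37 of 65 in blood.

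The brain libraries of APP-PS1 and WT mice were compared to ask whether the transgenic strain alters CD8+ T cells in the tissue. No gene was called by edgeR's quasi-likelihood test, and none by DESeq2 or by limma voom. At an unadjusted p under 0.05 there were 98 genes, against 118.3 expected by chance. Cxcr6 averaged 852 ± 119 CPM (SD, n = 4) in APP-PS1 brain and 761 ± 291 CPM (SD, n = 5) in WT brain, a log2 fold change of 0.16 (SE 0.29, adjusted p = 0.999). Ccl5, Isg20 and Xcl1 had log2 fold changes of -0.18, 0.12 and -0.46, and Cd8a and Cd3e of -0.30 each (adjusted p = 0.999). Larger changes did not pass either. Cd69 averaged 193 ± 180 CPM in APP-PS1 brain, with 462 CPM in replicate 3, and 38.998 ± 34.3 CPM in WT brain, without overlap between the groups (log2 fold change 2.05, unadjusted p = 0.00186, adjusted p = 0.999, or 0.66 with sex as a term). Igkc had a log2 fold change of 1.86 and Ikzf2 one of -1.77 (adjusted p = 0.999 for both). No list passed: the smallest adjusted p, 0.236, was shared by effector, adhesion, interferon and red cell genes, whose medians were -0.18, -0.33, 0.11 and -0.94. Among marker sums, B cell markers were at 298 ± 212 CPM in APP-PS1 brain and 83.9 ± 12.4 CPM in WT brain and CD4 and regulatory T cell markers at 35.3 ± 41.8 and 176 ± 114 CPM, neither passing after adjustment (exact permutation p = 0.0159 and 0.0317, adjusted p = 0.270 for both). Igkc held 57 of the 91 B cell counts in APP-PS1 brain, and Ikzf2 70 of the 87 CD4 and regulatory T cell counts in WT brain. In simulated counts of these libraries, 28% of genes changed 2-fold, 66% changed 4-fold and 92% changed 8-fold were recovered, so differences of about 2-fold in single genes were mostly not detectable at this depth.

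Between the blood libraries of the 2 strains, 1 gene was called. Ccr7 averaged 503 ± 119 CPM (SD, n = 3) in APP-PS1 blood and 79.0 ± 38.0 CPM (SD, n = 5) in WT blood, a log2 fold change of 2.54 (SE 0.51, adjusted p = 0.0169), with all 3 APP-PS1 libraries above all 5 WT libraries. DESeq2 also called 1 gene and limma voom 2, and 190 genes had an unadjusted p under 0.05. The effector list was lower in APP-PS1 blood, with a median of -0.82 and 14 of 17 genes negative (camera, adjusted p = 0.00482), while the naive list was higher, with a median of 0.51 and 8 of 11 positive (adjusted p = 0.0275). Immediate early genes had a median of 0.70 (adjusted p = 0.0340). None of the 3 lists passed with an estimated correlation (adjusted p = 0.107, 0.239 and 0.107), with sex as a term (0.334, 0.162 and 0.279) or with female libraries only (0.570, 0.570 and 0.801). The naive list was also lost without a filter (adjusted p = 0.0688), with the 5 CPM filter (0.0857), after thinning (0.214) and with fry (0.227). The median of immediate early genes turned to -0.12 without a filter (adjusted p = 0.623) and to -0.34 with the 5 CPM filter (adjusted p = 0.583), and the call was also lost with voom (0.0535), after thinning (0.128) and without 2 libraries that stood apart (0.0719). The effector list did not pass without WT blood replicate 5 (median -0.35, adjusted p = 0.0770). The naive list did not pass without that library (0.22, adjusted p = 0.347) or without APP-PS1 blood replicate 2 (0.18, adjusted p = 0.313) or 3 (0.22, adjusted p = 0.140). The immediate early list did not pass without any one APP-PS1 blood library, WT blood replicate 1, 4 or 5 or WT brain replicate 5 (adjusted p up to 0.687 without APP-PS1 blood replicate 2, where its median was -0.14). Summed CPM of naive, effector, microglia and myeloid lists differed at an exact permutation p of 0.0357, the smallest possible, and an adjusted p of 0.152, but Ccr2 held 3 of 3 and 143 of 154 counts of the myeloid list and Ccl5 3308 of 4485 and 27562 of 34867 counts of the effector list. No other list passed camera (adjusted p of at least 0.157). Of the effector, naive and immediate early lists 0, 1 (Ccr7) and 0 genes were called, or 2, 1 and 2 when adjusted over the list alone. Ccl5 and Id2, effector genes, had log2 fold changes of -0.82 and -0.97, and the chemokine receptor Ccr2 one of -3.34, all short of the threshold (adjusted p = 0.176, 0.186 and 0.125). Pdcd1 had 0 counts in APP-PS1 blood and 23 in WT blood, at least 1.67-fold lower (adjusted p = 0.483). The call of Ccr7 ended with sex as a term (log2 fold change 2.33, adjusted p = 0.539) and without any one APP-PS1 blood library or WT blood replicate 1, 2, 3 or 5 (adjusted p up to 0.268). It also ended without a filter and with a filter of 5 CPM (adjusted p = 0.100 and 0.0641), after thinning and with female libraries only (adjusted p = 0.985 and 0.637). The log2 fold change stayed at 2.01 or above in these fits (2.26, 2.27, 2.01 and 2.31) and at 2.35 to 2.74 with a library left out.

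The test of whether the brain against blood difference itself depended on strain called 1 gene, Igkc, with an interaction of 5.56 on the log2 scale (SE 1.09, adjusted p = 0.0104); 117 genes had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. Igkc (chromosome 6, 70726435 to 70726966 in GRCm38) averaged 206 ± 83.7 CPM in WT blood and 49.4 ± 21.8 CPM in WT brain (SD, n = 5), against 15.3 ± 13.3 CPM (SD, n = 3) in APP-PS1 blood and 176 ± 214 CPM (SD, n = 4) in APP-PS1 brain. The APP-PS1 blood value came from 2 counts, fewer than the floor of 3 counts, so the size of the interaction is uncertain. One library, APP-PS1 brain replicate 2, held 492 CPM, and without it the interaction was 4.13 (adjusted p = 0.656). Without APP-PS1 blood replicate 1 it was 5.03 (adjusted p = 0.0828). Ccr7, at -2.53, did not pass (adjusted p = 0.862), so its fall from blood to brain was not shown to differ between strains. The interferon list leaned to a larger rise in APP-PS1 mice without passing (median 0.84, 13 of 14 positive, adjusted p = 0.0669), and passed without APP-PS1 brain replicate 2 or WT blood replicate 2, 3 or 4 (adjusted p down to 0.0214). Immediate early genes leaned the other way (median -0.61, adjusted p = 0.186) and passed without WT blood replicate 2 or 3 (-0.63 for both, adjusted p = 0.0443 and 0.0484).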

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

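All tests of explanations in this part other than the splits of the samples were chosen after the results were seen. The splits for the contrast averaged over strains also came after, since that contrast was itself added then. Of 238 groups of values examined for a library standing apart from the rest, 18 met the criterion. The APP-PS1 blood libraries were not examined in this way. For independent, normally distributed values chance gives about 1 in 20, or 11.9. Here many values are low counts, and a single library with a count among zeros always meets the criterion. Some genes also enter list sums, so the number given by chance is not known.

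Several values of one library stood apart together. WT blood replicate 5 held 2131 CPM of Gzma (111 to 639 in the other 4), 884 CPM of Gzmb (79.9 to 275), 295 CPM of Klrg1 (60.6 to 128), 146839 CPM of Actb (66693 to 87123) and 9.82 summed CPM of astrocyte markers, which is 1 count. In WT blood, replicate 1 had 97.8 CPM of Rgs1 (29.5 to 44.6 in the others), replicate 2 had 63.3 CPM of Ctla4, replicate 3 had 11.1 CPM of Zfp683, a single count, and replicate 4 had 767 CPM of Tsc22d3 (238 to 387) and 367 summed CPM of oligodendrocyte markers (234 to 261). In WT brain, replicate 2 had 200.1 CPM of Klf2 (114 to 137), replicate 3 had 78.2 CPM of Lag3 (13.6 to 23.5), replicate 4 had 622 CPM of Xcl1 (352 to 395) and 121 CPM of Hbb-bt (0 to 20.9), and replicate 5 had 20.9 CPM of S1pr5 against 0. In APP-PS1 brain, replicate 3 had 462 CPM of Cd69 (94.0 to 109), and replicate 4 had 149 CPM of Hba-a1 (0 to 23.4) and 39.2 CPM of Hbb-bt against 0.

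The brain against blood change of Igkc differed between strains, with an interaction of 5.56 on the log2 scale, and was the 1 gene called. Of 100 regroupings of strain within tissue, 6 gave at least 1 called gene, with at most 2, so chance cannot be excluded.

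The 18 genes called between WT brain and WT blood exceeded the highest other count, 1, and 1 of 100 splits, the real one, gave as many. An arbitrary split of the libraries is thus an unlikely source of so many calls. The same held for the 13 genes of APP-PS1 brain against blood, where 1 of 35 splits, the real one, gave 13 and the highest other called 4. It held too for the 62 genes averaged over strains, where 1 of 100, the real one, gave 62 and the highest other called 6. These unadjusted shares are the smallest the tests could reach, and they do not bear on any single gene. For APP-PS1 against WT brain, with 0 genes called, 100 of 100 splits gave as many, with at most 1. With 0 called no other outcome was possible, so this share decides nothing. For APP-PS1 against WT blood, with 1 gene called, 3 of 56 splits gave as many, with at most 2, so chance cannot be excluded.

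Interferon response genes were higher in brain in both strains, with a median log2 fold change of 1.31. RNA of microglia is argued against: 7 genes abundant in microglia had 5 counts in all brain libraries together (exact Poisson interval 1.62 to 11.7), while the interferon list exceeded its blood level by 1434 counts. RNA of monocytes or neutrophils is argued against too, since 11 of their markers, all listed ones but Ccr2, which T cells also carry, had 3 counts in the brain libraries (interval 0.62 to 8.77). Selection for CD8+ cells would also remove such cells, though its gate is not given in the sources used here. Depth is argued against, as the median stayed at 0.95 or above in 20 thinnings of all libraries to 27646 counts. Stress of dissociation cannot be told apart from a difference between tissues, since brain alone was dissociated. Immediate early and heat shock genes had a median of -0.0365 (bootstrap interval -0.55 to 0.36), but they went both ways, from -1.56 for Ier2 to 1.76 for Dusp2, so this median decides nothing. A biological difference between tissues stays open and was not tested.

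The haemoglobin genes were 13.4 to 30.5 times lower in brain in the fitted values of both strains, and Hbb-bt was not called in APP-PS1 mice. RNA of red cells left in the blood libraries could account for this. The 4 genes fell by amounts that differed by at most 0.53 on the log2 scale within a strain. This closeness decides nothing, since the standard errors averaged 0.74 and reads of the paired genes cannot be told apart with certainty. A red cell lysis step named in the labels' protocols applied to the blood samples. A biological difference between tissues stays open and was not tested.

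By camera at the preset correlation, naive genes were higher and effector genes lower in APP-PS1 blood than in WT blood, the 2 medians differing by 1.33, but neither list passed with an estimated correlation (adjusted p = 0.239 and 0.107). Without WT blood replicate 5 neither passed, and the medians were 0.22 and -0.35 in place of 0.51 and -0.82. Depth as the whole cause is argued against, since the difference stayed at 0.5 or above in 19 of 20 thinnings (0.41 to 1.49). One such thinning ended the call of the naive list, whose median went from 0.51 to 0.30 with 6 genes tested in place of 11, while the effector list still passed at -0.70. Sex cannot be told apart from strain: with sex as a term neither list passed (adjusted p = 0.162 and 0.334), the difference was 0.69 (bootstrap interval 0.06 to 1.92), and 1 APP-PS1 blood library is female. A different share of naive cells may underlie the pattern in either case and was not tested apart from these lists.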

How the results depend on the processing

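The contrast averaged over strains and the fit without 2 libraries were chosen after the results were seen. The direction of a list was that of its test, which at times differed from the sign of its median; values short of the threshold in both fits were counted as unchanged. Of 11996 values of 442 named gene results under the alternatives, 11460 kept their side, 503 lost and 33 gained a call and 0 reversed. Of 2405 list values, 2317 kept it, 57 lost and 29 gained a call and 2 reversed. The 2 reversals were the checkpoint list in WT brain against blood, with a median of -0.23 without a filter (adjusted p = 0.828) and -0.54 with a filter of 5 CPM in 3 libraries (adjusted p = 0.914), where more genes at low counts entered. APP-PS1 against WT brain gave 0 genes under every alternative run. WT brain against blood, with 18 genes, gave 6 after thinning, where 752 genes were tested, and 12 to 21 with a library left out. APP-PS1 brain against blood, with 13, gave 21 with DESeq2, 7 with voom and 5 after thinning. It gave 4 with female libraries only (1 APP-PS1 library per tissue, assumed to vary like the other groups) and 8 without mitochondrial, ribosomal and haemoglobin genes. It ranged from 8 without APP-PS1 blood replicate 2 to 22 without replicate 3. APP-PS1 against WT blood, with 1, gave 2 with voom, 5 without a filter, 7 with the 5 CPM filter and 4 with only the groups compared. It gave 0 after thinning, with sex as a term and with female libraries only. It gave 3 without mitochondrial, ribosomal and haemoglobin genes and 4 without the 2 libraries that stood apart (APP-PS1 brain replicate 1 and WT blood replicate 4, chosen after seeing the data). With a library left out it ranged from 0 (APP-PS1 blood replicates 1 and 3, WT blood replicates 1, 2, 3 and 5) to 3 (WT brain replicate 3). The interaction, with 1, gave 0 with DESeq2, voom, thinning and female libraries only, and 0 to 1 with a library left out, 0 without APP-PS1 blood replicate 1 or APP-PS1 brain replicate 2. The average over strains, with 62, gave 36 with voom (9 higher, 27 lower), 8 after thinning and 18 with female libraries only, and 45 to 66 with a library left out. Thinning, female libraries and removed genes leave fewer counts, libraries or genes; for the other changes the cause was not tested. No paired analysis was possible because no label ties a brain and a blood library to one mouse. Depth limits single genes to large changes.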

Other observations

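All genes and values in this part were chosen after they were seen. Among genes called for the contrast averaged over strains and not described above, the inflammatory protease Casp1 rose in brain by 1.35 on the log2 scale (SE 0.34, adjusted p = 0.0120) and the death ligand Tnfsf10 by 2.02 (SE 0.51, adjusted p = 0.0132) by edgeR's quasi-likelihood test. Tsc22d3, a glucocorticoid-induced gene, fell by 1.14 (adjusted p = 0.0120) and the transcription factor Ets1 fell by 0.99 (adjusted p = 0.000731). Casp1 and Tnfsf10 lost their calls with limma voom, Casp1 also without APP-PS1 blood replicate 1 or 2 or APP-PS1 brain replicate 3 (adjusted p up to 0.0785) and Tnfsf10 without APP-PS1 brain replicate 4 (adjusted p = 0.108).

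A scaling plot of the 500 most variable genes set APP-PS1 brain replicate 1, the shallowest library at 27646 counts, apart on both axes, at -1.35 and -1.26. The share of counts on Actb ranged from 2.24% in APP-PS1 blood replicate 1 to 14.7% in WT blood replicate 5.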
